A study of Mus musculus with 21 samples.

How the data were processed

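Whole testes of C57BL6 male mice, wild type or Mageb4 knockout, were taken without heat or 72 h after heat shock, per the labels' protocols. The temperature and length of the heat shock, the age of the animals and the knockout allele are not given in the sources used here. RNA was extracted with Trizol, libraries were made with the TruSeq stranded mRNA kit and sequenced on an Illumina HiSeq, per the labels' protocols. STAR and the mm10 genome were used, per the submitters' processing notes. The version of STAR, the gene annotation and the tool that turned alignments into abundances are not given in the sources used here. The deposited values are TPM (transcript abundances scaled to a fixed total), computed by the authors, with the same sum in each library. TPM keeps no depth, so the number of reads per library and the counting error of low genes are unknown. Precision was judged from the replicates: Pearson correlation within groups was 0.971 to 0.994, and the median SD of log2(TPM + 1) per gene was 0.110 in each unheated group, 0.147 in heated wild type and 0.179 in the heated knockout. Between 17243 and 18547 genes per library reached 1 TPM, and the 10 most abundant genes held 5.61% to 13.4% of the total. No 2 libraries were identical.

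Samples were grouped as wild-type control (n = 6), knockout control (n = 6), wild-type heat (n = 4) and knockout heat (n = 5), and the replicates were taken as biological, 1 animal each, per the labels' protocols. The table held 55573 entries for 55453 symbols, of which 117 symbols stood on more than 1 entry (237 entries) and were kept apart. Of the symbols, 54510 (98.3%) are names in GENCODE M21, which was used for coordinates on mm10 and for chromosomes, and may not be the annotation behind the deposited values. Some values of exactly 0 can be failed estimates, as for mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8, which were listed at 0 in most libraries.

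Values were transformed to log2(TPM + 1), and genes with a mean of at least 1 TPM over the 21 libraries were kept, 18977 in number. All libraries entered 1 linear model of group means with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. The 5 comparisons were heat against control in wild type, heat against control in the knockout, knockout against wild type without heat, knockout against wild type after heat, and the difference between the 2 heat effects. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and genes were called at an adjusted p under 0.05. Errors given with log2 fold changes are moderated standard errors, and errors given with TPM are SD between animals. Fold changes in TPM are ratios of group means. For Mageb4, G3bp1 and G3bp2, differences of mean log2(TPM + 1) were also tested by 2-sided exact permutation in each comparison of 2 groups, with adjustment over the 12 tests. Agreement of the 2 heat effects was measured by correlation and slope across genes, with a jackknife error over libraries and no p-value, since genes are not independent replicates.

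There were 27 gene lists, written from textbook knowledge: MAGE family, stress granule components, heat shock response, unfolded protein and integrated stress response, p53 targets and apoptosis, oxidative stress response, undifferentiated spermatogonia, differentiating spermatogonia, early meiotic prophase, pachytene and diplotene spermatocytes, round spermatids, elongating and condensing spermatids, piRNA pathway, Sertoli cells, blood-testis barrier and junctions, Leydig cells, cholesterol biosynthesis, peritubular myoid and smooth muscle, macrophages and other leukocytes, inflammatory cytokines, interferon-stimulated genes, endothelium, extracellular matrix, immediate early genes, epididymis, red blood cells and mitochondrially encoded genes. Lists with at least 5 measured genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. The same test was run with a correlation estimated per list. Members were counted as higher or lower with adjustment over all genes and over the list alone.

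The genes named in each comparison followed a rule. They were Mageb4, G3bp1, G3bp2 and Ddx5, and the 6 largest rises and 6 largest falls in log2(TPM + 1). The rises and falls were taken among called genes with a mean of at least 5 TPM and, for comparisons of 2 groups, no overlap between them, leaving out predicted genes and clone names. To these came the 2 members with the largest moderated t in the direction of each called list, and the 2 with the largest absolute t for the MAGE, stress granule and heat shock lists. For 1 gene that the rule picked in the difference of the heat effects, the result is not reported. Further genes named where a count was 5 or fewer (Cst9, Rhox5 and Dhh), and Crisp1 and the other epididymal genes, were chosen after their values were seen. The 5 comparisons, their tests, the 27 lists, the gene rule and the alternatives were fixed before the data were examined, and the tests of explanations were added later.

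The alternatives were a pseudocount of 0.1 or 5, no filter on low values (39589 genes) or a mean of at least 5 TPM (13162 genes), median-of-ratios scaling or quantile normalization, a robust fit with array weights, a fit of only the groups compared, the replicate number as a block, an estimated inter-gene correlation for the lists, and leaving out each library in turn. For each comparison, 100 splits of the same samples, the real one included, were fitted. The procedure was tested on simulated data with 1 spread per gene, pooled over the real groups, and 200 changed genes among 18977. Genes were drawn independently. The simulation held neither the unequal spread of the groups, nor correlation between genes, nor the large share of genes called after heat. Its rates therefore hold for that setting only. At a true log2 change of 0.5 (67 genes) it recovered 71.6% for heat in wild type, 67.2% for heat in the knockout, 71.6% and 65.7% for the genotype comparison without and after heat, and 44.8% for the difference of the heat effects. At a true log2 change of 1 (67 genes) it recovered 94.0%, 92.5%, 97.0%, 97.0% and 88.1% in the same order, and at 2 (66 genes) 98.5%, and 100% for the difference of the heat effects. False calls made up 4.35%, 2.27%, 5.32%, 3.87% and 5.49% of calls, and of the simulated lists the shifted one was called each time and 0 of the others. Figures were made with Python 3.11.15 and matplotlib 3.10.9. All 21 libraries were used and none was left out of the results given.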

Results

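Gene expression was measured by RNA sequencing in 21 whole testes of C57BL6 mice. Mageb4 knockout and wild-type animals were compared without heat and 72 h after heat shock, to find how loss of this gene affects the testis transcriptome at rest and after heat. Mageb4 is an X-linked gene of the MAGE family, many of whose members are expressed mainly in the germline and in tumours, and the title of the series concerns repression of G3BP, a core protein of stress granules. There were 6 unheated wild-type, 6 unheated knockout, 4 heated wild-type and 5 heated knockout libraries, prepared as separate biological replicates. The values are TPM, so sequencing depth is unknown, and 18977 genes with a mean of at least 1 TPM were tested. The first principal component of log2(TPM + 1) held 86.4% of the variance, with unheated libraries from -85.3 to -60.9, heated knockout from 28.7 to 72.9 and heated wild type from 146.7 to 187.9. Changes given as fold are ratios of group mean TPM, and those given in log2 are on the log2(TPM + 1) scale, which understates the change of low genes, with their standard error where one is printed. A median-of-ratios scaling shifts the log2 values by -0.31 for heat in wild type, -0.09 for heat in the knockout, -0.03 and 0.19 for knockout against wild type without and after heat, and 0.22 for the difference of the heat effects. Changes of this size or smaller depend on the scaling.

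The targeted gene was checked in each library first. Mageb4 (ENSMUSG00000035427.18) lies on chromosome X at 86250254 to 86305093 of mm10, on the minus strand, and its coding sequence lies within 1 exon, at 86250754 to 86252421. It stood at 1.80 ± 0.173 TPM (SD, n = 6) in unheated wild type and 0.0467 ± 0.0361 TPM (n = 6) in the unheated knockout, with no overlap between the 6 libraries of each. After heat it was 8.03 ± 0.222 TPM (n = 4) in wild type and 0.120 ± 0.0224 TPM (n = 5) in the knockout. The genotype differences had 2-sided exact permutation p = 0.00216 without heat and 0.00794 after heat (0.00952 and 0.0106 after adjustment over 12 such tests), each the smallest p these group sizes allow. After heat Mageb4 was 4.46-fold higher in wild type (exact permutation p = 0.00476, adjusted 0.00952, all 4 heated libraries above all 6 unheated). X-linked genes as a set also rose there (median log2 fold change 1.33). A rise per cell was not told apart from a changed cell mix. In the knockout the residual value went from 0.0467 to 0.120 TPM (exact permutation p = 0.0108, adjusted 0.0118; limma adjusted p = 0.116). The part of the gene that was deleted is not given in the sources used here.

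G3bp1 and G3bp2 encode the RNA-binding proteins on which stress granules assemble. G3bp1 lies on chromosome 11 at 55469685 to 55504838 and G3bp2 on chromosome 5 at 92052146 to 92083719 of mm10, both protein-coding. In whole-testis TPM both transcripts rose after heat, and by more in wild type. Marker lists of germ and somatic cells also moved strongly (below), so a change per cell cannot be told from a changed cell mix. The proteins were not measured here. G3bp1 went from 12.9 ± 0.357 to 31.3 ± 2.04 TPM (SD, n = 6 and 4) in wild type and from 13.9 ± 1.304 to 20.002 ± 1.94 TPM (n = 6 and 5) in the knockout. G3bp2 went from 45.9 ± 2.94 to 154 ± 14.0 TPM in wild type and from 50.4 ± 1.44 to 82.4 ± 10.8 TPM in the knockout. The exact permutation p of the heat effect was 0.00476 for each gene in wild type, and 0.00433 for G3bp1 and 0.00216 for G3bp2 in the knockout. After heat both were lower in the knockout, G3bp1 1.57-fold and G3bp2 1.87-fold (exact permutation p = 0.00794 each, adjusted 0.0106), with no overlap between genotypes. The heat effects themselves differed by -0.72 ± 0.10 log2 (limma adjusted p = 9.04e-07) for G3bp1 and -1.04 ± 0.11 (3.57e-08) for G3bp2. Without heat the knockout means were 1.08 and 1.10 times the wild-type means. Exact permutation gave p = 0.0281 and 0.0108 (adjusted 0.0281 and 0.0118), while the moderated test across all genes gave adjusted p = 0.517 and 0.357. Knockout control replicate 6 held the highest G3bp1 value of its group, 16.5 TPM against 12.9 to 13.7 in the others. Ddx5, an RNA helicase on chromosome 11 at 106780355 to 106789185, fell after heat in both genotypes, from 649 ± 17.9 to 455 ± 13.2 TPM in wild type and from 641 ± 16.8 to 361 ± 48.7 TPM in the knockout.

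**Figure D1:**
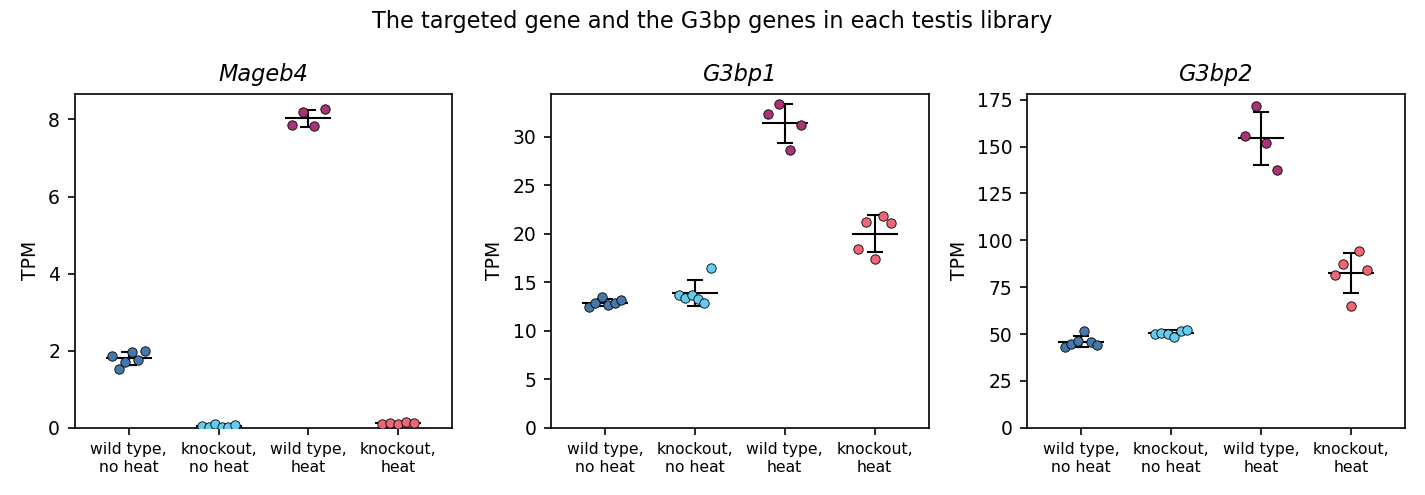
TPM of Mageb4, G3bp1 and G3bp2 (vertical axes) in each of the 21 libraries, by group. Points are libraries and black marks are group means with SD; Mageb4 stays at or below 0.15 TPM in every knockout library, and heated wild type holds the highest values of all 3 genes.

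Heat in wild-type testes was followed by a fall of transcripts of meiotic and haploid germ cells and a rise of transcripts of the somatic cells. Of the 25 round spermatid genes 23 fell and 0 rose (median log2 fold change -4.44, camera adjusted p = 3.59e-06), and of the 27 pachytene and diplotene spermatocyte genes 25 fell and 2 rose (-2.85, adjusted p = 3.59e-06). All 20 Sertoli cell genes rose (median 2.72, adjusted p = 3.59e-06), as did all 14 Leydig cell genes (2.00, adjusted p = 0.000548). For these 4 lists the adjusted p = 0.385 with an estimated correlation. Catsper2, a subunit of the sperm calcium channel, fell from 194 ± 6.72 to 8.26 ± 2.54 TPM (SD, n = 6 and 4). Crem, a transcription factor of haploid germ cells, fell from 379.9 ± 6.91 to 79.0 ± 7.59 TPM. Among the spermatocyte genes the meiotic cyclin Ccna1 fell 17.0-fold and the phosphatase Cdc25c 7.03-fold. The Sertoli cell gene Cst12 rose 8.45-fold to 1934 ± 109.8 TPM and Tsx 7.12-fold. In the Leydig cell list Cyb5a, a cofactor of androgen synthesis, rose 7.14-fold and the steroidogenic enzyme gene Hsd3b1 6.61-fold.

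Other somatic lists moved the same way, each with adjusted p = 0.385 with an estimated correlation. Of the 20 genes of macrophages and other leukocytes 19 rose and 1 fell (median 2.02, camera adjusted p = 0.000548), with Mrc1, the mannose receptor, up 7.62-fold and Fcer1g 8.27-fold. All 12 endothelial genes rose (median 1.51, adjusted p = 0.00226), among them Pecam1 and Cdh5. Of the 9 peritubular myoid and smooth muscle genes 8 rose and 1 fell (median 1.37, adjusted p = 0.0335; 0.0991 with a filter of 5 TPM), with Mylk and Myl9 leading. In the extracellular matrix list 17 of 18 genes rose and 1 fell (adjusted p = 0.000548), with Sparc up 9.40-fold and Dcn 9.38-fold. Of 13 blood-testis barrier and junction genes 10 rose and 2 fell (adjusted p = 0.0335), with Gja1 and F11r leading. All 9 interferon-stimulated genes rose (median 1.92, adjusted p = 0.00338), with Oasl2 up 6.84-fold and Ifih1 8.71-fold. Among the stress lists, 15 of 18 genes of the unfolded protein and integrated stress response rose and 2 fell (adjusted p = 0.00246), Xbp1 and Psat1 leading. In the oxidative stress list 13 of 16 rose and 3 fell (adjusted p = 0.00779), Gsta4 by 9.38-fold and catalase, Cat, by 5.28-fold. In the list of p53 targets and apoptosis 13 of 17 rose and 4 fell (adjusted p = 0.0428), including Ccng1 and the cell cycle inhibitor Cdkn1a. The p53 list was lost with a filter of 5 TPM (adjusted p = 0.223) and with quantile normalization (0.0558). All 3 stress lists had adjusted p = 0.385 with an estimated correlation. A change per cell was not told apart from a changed cell mix for these lists. The same holds for the interferon, MAGE and mitochondrial lists, and in the comparisons below. In the piRNA pathway 16 of 19 genes fell and 2 rose (median -1.85, adjusted p = 0.0017; adjusted p = 0.4 with an estimated correlation), Tdrd7 and Henmt1 leading.

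The MAGE family rose as well: 17 of 20 genes were higher and 2 lower (median 2.25, camera adjusted p = 0.000373; adjusted p = 0.385 with an estimated correlation). Mageb18 rose from 1.17 ± 0.155 to 18.3 ± 0.907 TPM and Magea5 from 1.22 ± 0.0847 to 14.0 ± 0.764 TPM (SD, n = 6 and 4). MAGE genes are close paralogs, and how reads shared between them were counted is not given in the sources used here. The 12 measured mitochondrially encoded genes included 10 that rose and 2 that did not pass (median 2.30, adjusted p = 0.0017; adjusted p = 0.385 with an estimated correlation), with mt-Nd1 up 13.1-fold to 14343 ± 1649 TPM and mt-Nd3 6.65-fold. Several mitochondrial genes, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8, were listed at 0 in most libraries, so single values of 0 in this table need not mean absence of the transcript. Of these, mt-Co3, mt-Atp6 and mt-Atp8 passed the filter through a few libraries and are among the 12. In heated wild type mt-Co3 stood at 15.81, 0.08, 0.41 and 51.73 TPM. The counts and tests of the mitochondrial list include these genes, here and in the comparisons below. The lists of stress granule components and heat shock genes did not pass camera. Of 26 stress granule genes 16 rose and 8 fell (adjusted p = 0.202), Fmr1 rising 7.99-fold and Ybx1, an RNA-binding protein, falling 4.00-fold. Of 21 heat shock genes 13 rose and 8 fell (adjusted p = 0.337), and the mitochondrial chaperones Hspd1 and Hspe1 rose 6.16-fold and 4.55-fold. Elongating and condensing spermatid genes were split, with 8 higher and 11 lower of 22 (adjusted p = 0.356; 0.0341 with quantile normalization). So were early meiotic prophase genes, with 12 and 11 of 25 (adjusted p = 0.907; the median was 0.16 and the mean -0.14). The remaining lists did not pass: undifferentiated spermatogonia (7 of 10 genes higher, adjusted p = 0.12), differentiating spermatogonia (7 of 10, 0.12), cholesterol biosynthesis (10 of 16, 0.506), inflammatory cytokines (5 of 6, 0.0626), immediate early genes (7 of 9, 0.106) and red blood cells (5 of 5, 0.0903). With no filter the lists of both spermatogonia, cytokines and red blood cells passed (adjusted p = 0.00772 to 0.0438), and cytokines also with median-of-ratios scaling (0.043). The epididymis list, with 4 measured genes, was too short to test.

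Over all genes, 8925 rose and 8460 fell, 91.6% of those tested, and 5863 and 5797 of them changed at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). With median-of-ratios scaling 7896 rose and 9482 fell, so which direction held the majority depended on the scaling. Genes are ranked here and below on the log2(TPM + 1) scale, on which genes near 0 TPM in 1 group rank lower than by TPM ratio. The largest rises were Timp1, a metalloprotease inhibitor (1.41 ± 0.224 to 144 ± 43.7 TPM), the cytokine receptor gene Tnfrsf12a (62.2-fold), Igfbp3 (56.6-fold), Serpina3n (37.5-fold), Spink8 and the mitochondrial ribosomal RNA mt-Rnr2 (20.1-fold). The largest falls on the log2(TPM + 1) scale, though not all by TPM ratio, were the flagellar tektin gene Tekt4 (217 ± 20.4 to 3.73 ± 3.57 TPM), Gtsf2, the actin-related Actl7b, Glipr1l1, Prr27 and Toporsl, each from 117.5 TPM or more to 13.9 TPM or less. The sizes of these falls depended on wild-type heat replicate 1, without which Tekt4 fell 110.4-fold in place of 58.2-fold and Actl7b 86.3-fold in place of 40.5-fold, and Gtsf2, Glipr1l1 and Prr27 also moved by over 1.5 times. The Spink8 rise rested mainly on wild-type heat replicate 3, at 1280.1 TPM against 11.52 to 17.97 TPM in the other heated wild-type libraries. Without that library its log2 fold change was 2.83 in place of 4.40, still past the threshold. The same library held 2126 TPM of the epididymal gene Crisp1, against at most 0.35 TPM in the other 3. Adjusted over the list alone, the counts of genes called in each list were the same as those given. None of the 16 called lists held with an estimated correlation.

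**Figure D2:**
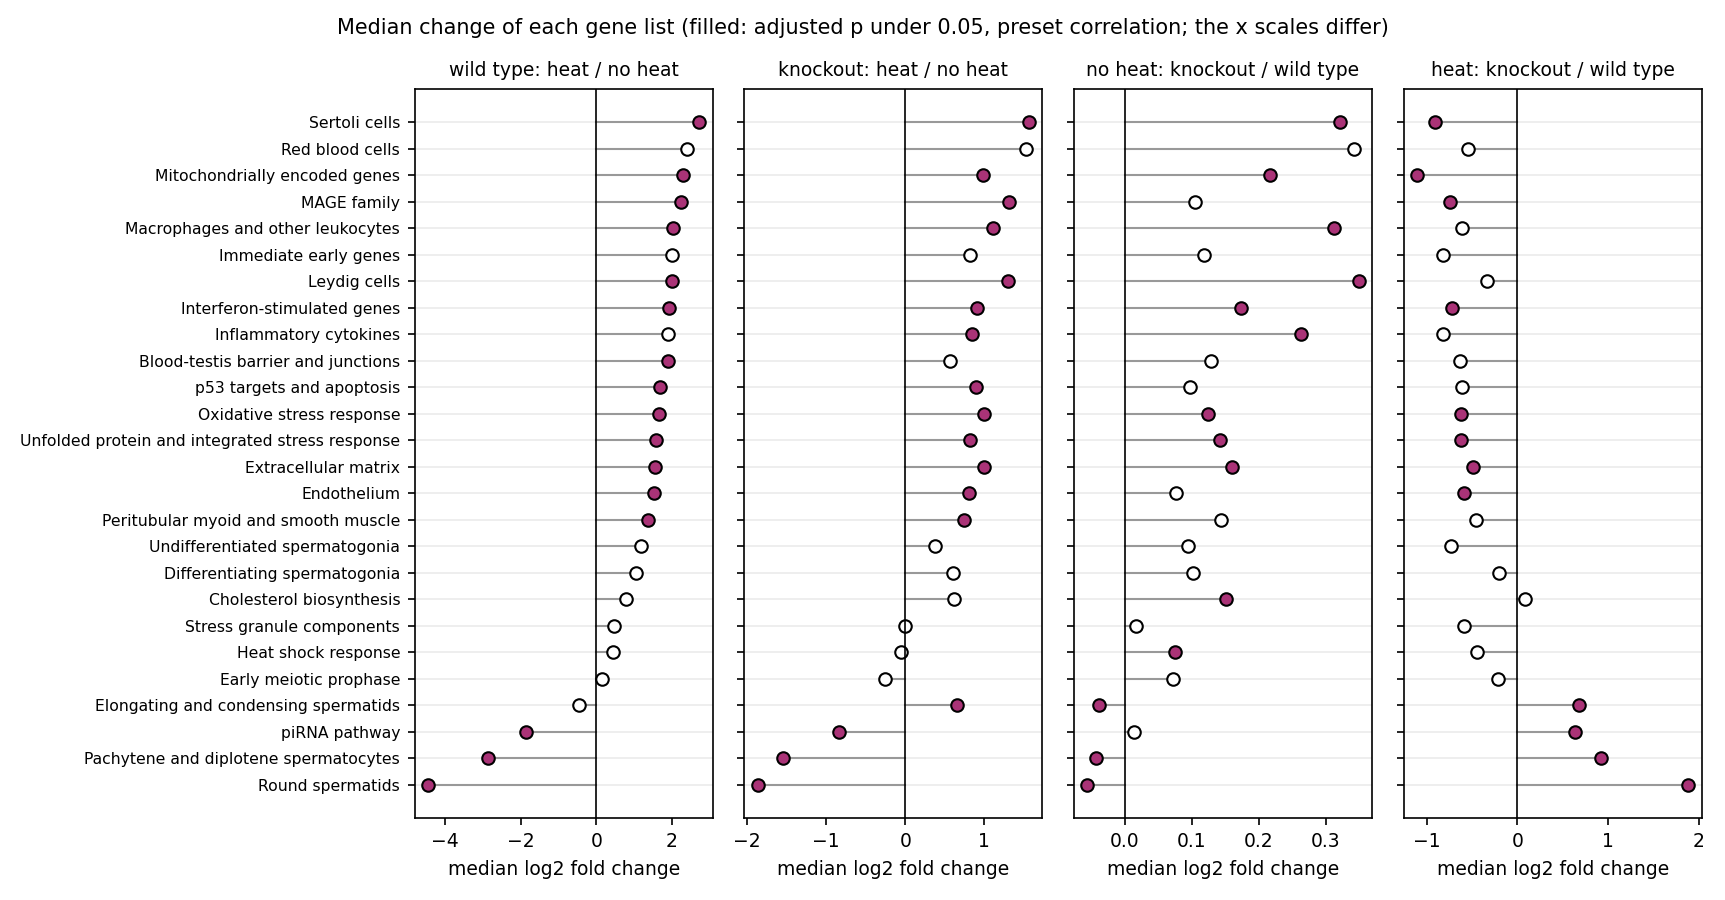
Median log2 fold change of the 26 tested gene lists (horizontal axes; each panel has its own scale) in 4 comparisons. Filled points are lists with camera adjusted p under 0.05 at the preset correlation; none of these held with an estimated correlation. Lists are ordered by their median in heated wild type, from round spermatids at -4.44 to Sertoli cells at 2.72.

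Heat in the knockout moved the Sertoli, Leydig, round spermatid and pachytene lists in the same direction, with smaller medians. All 20 Sertoli cell genes rose (median 1.56, camera adjusted p = 1.44e-07) and all 14 Leydig cell genes rose (1.303, 9.04e-05). Of the 25 round spermatid genes 20 fell and 3 rose (median -1.86, adjusted p = 0.00129), and of the 27 pachytene and diplotene genes 24 fell and 2 rose (-1.54, 5.56e-06). The Sertoli and Leydig lists had adjusted p = 0.328 with an estimated correlation, the round spermatid list 0.444 and the pachytene list 0.371. Cst12 rose 3.44-fold, Tsx 3.12-fold, Hsd3b1 3.27-fold and Hsd3b6 3.08-fold. Catsper2 fell from 189 ± 8.42 to 26.3 ± 8.95 TPM (SD, n = 6 and 5), Crem 2.70-fold, Ccna1 7.03-fold and the spindle kinase gene Aurka 4.46-fold. Genes of elongating and condensing spermatids went up: 15 of 22 rose and 3 fell (median 0.66, adjusted p = 0.00494; with quantile normalization, median 0.16, adjusted p = 0.32; adjusted p = 0.444 with an estimated correlation). In wild type the median of this list was -0.45, and camera did not pass. The junction list did not pass in the knockout (7 higher and 3 lower of 13, adjusted p = 0.0668), except with quantile normalization (0.0497) and no filter (0.0334), and the direct test of its difference from wild type did not pass (adjusted p = 0.0626; 0.0484 with median-of-ratios scaling and 0.00674 with no filter). Within the elongating spermatid list the antizyme gene Oaz3 rose from 2878 ± 65.996 to 5260.1 ± 358 TPM and Tppp2 2.10-fold.

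In the knockout, 19 of 20 leukocyte genes, 11 of 12 endothelial genes, 9 of 9 peritubular myoid genes and 17 of 18 extracellular matrix genes rose, with camera adjusted p of 0.000131, 0.00196, 0.00484 and 0.000131. Each of the lists in this paragraph that passed had adjusted p = 0.328 to 0.444 with an estimated correlation. Leading members were Fcer1g (3.03-fold), Mrc1, Pecam1, Cldn5, Myl9, Acta2, Bgn and Sparc (3.59-fold). All 9 interferon-stimulated genes rose (adjusted p = 0.00327), Oasl2 and Usp18 leading, and 5 of 6 inflammatory cytokine genes rose (adjusted p = 0.0415; 0.066 with quantile normalization), including Nfkbia and Lcn2. The stress lists of the unfolded protein response (13 of 18 higher, adjusted p = 0.00238), oxidative stress (11 of 16, 0.0193) and p53 targets (13 of 17, 0.00806) rose, with Xbp1, Psat1, Sod1, Gsta4, Ccng1 and Pmaip1 leading. In the MAGE family 16 of 20 genes rose and 3 fell (median 1.31, adjusted p = 9.04e-05), Magea8 and Magea5 leading at 4.96-fold and 4.99-fold. In the piRNA pathway 17 of 19 fell (adjusted p = 0.000344), among them Tdrd7 and Dnmt3l, and 9 of 12 mitochondrially encoded genes rose (adjusted p = 0.00236), mt-Nd3 by 2.82-fold and mt-Nd1 by 3.67-fold. Stress granule components were evenly split, 11 higher and 11 lower of 26 (adjusted p = 0.864), with Atxn2l and Ybx1 falling 3.62-fold and 1.80-fold. Heat shock genes were split 9 to 8 (adjusted p = 0.803), with Hspe1 and Hspd1 up 2.42-fold and 2.63-fold. Differentiating spermatogonia did not pass (9 of 10 higher, camera adjusted p = 0.0604), except with no filter (0.0132) and with the replicate number as a block (0.0341).

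Over all genes, 7833 rose and 7875 fell in the knockout after heat (82.8%), 2373 and 3216 of them at least 2-fold. With median-of-ratios scaling 7322 rose and 8487 fell, and with quantile normalization 8494 rose and 7344 fell, so the majority direction depended on the scaling. The largest rises were Timp1 (2.10 ± 0.477 to 30.3 ± 15.4 TPM), the ferritin-like pseudogene Fthl17-ps3, Igfbp3, Serpina3n, Tnfrsf12a and Wfdc18. The largest falls were the fatty acid hydroxylase gene Fa2h (55.3 ± 1.11 to 2.81 ± 2.09 TPM), Glipr1l1, Dydc1, Spdye4c, Glipr1l3 and Prr27. Adjusted over the list alone, 2 in place of 3 genes of the junction list were lower, and no other count differed. None of the 17 called lists held with an estimated correlation.

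Without heat, knockout and wild-type testes differed little, and most of the genes that differed were higher in the knockout. Sertoli cell genes were higher as a list (median log2 difference 0.32, camera adjusted p = 2.6e-12; adjusted p = 0.318 with an estimated correlation), with 5 of 20 genes called (Cst12, Tsx, Cst9, Rhox5 and Dhh), or 16 when adjusted over the list alone. Knockout replicate 6 stood apart on this list (mean log2 5.633, others 5.218 to 5.32). Leydig cell genes were higher too (median 0.35, adjusted p = 1.23e-08; adjusted p = 0.318 with an estimated correlation; 3 of 14 called, Ptgds, Hsd3b1 and Hsd3b6, and 11 adjusted over the list alone). Cst12 stood at 229 ± 17.9 TPM in wild type and 297 ± 23.9 TPM in the knockout (SD, n = 6 each), Tsx at 45.0 ± 3.25 and 57.0 ± 5.14 TPM. The prostaglandin D synthase gene Ptgds stood at 483 ± 55.1 and 667 ± 88.4 TPM, and Hsd3b1 at 57.2 ± 2.91 and 79.1 ± 15.4 TPM. Genes of macrophages and other leukocytes had a median of 0.31 (adjusted p = 3.35e-07; adjusted p = 0.4 with an estimated correlation), with 1 of 20 called, Fcer1g, and 13 adjusted over the list alone; Csf1r did not pass over all genes (adjusted p = 0.0515). Knockout replicate 3 stood apart on this list (3.851, others 3.212 to 3.447). Lists of later germ cells lay slightly lower: round spermatids -0.06 (adjusted p = 0.00599), pachytene and diplotene spermatocytes -0.04 (0.00601) and elongating spermatids -0.04 (0.00601), each with adjusted p = 0.567 with an estimated correlation. With quantile normalization they did not pass (adjusted p = 0.154, 0.145 and 0.348). The earlier germ cell lists had positive medians and did not pass: undifferentiated spermatogonia 0.09 (0.244), differentiating spermatogonia 0.10 (0.194; 0.0348 with no filter) and early meiotic prophase 0.07 (0.281; 0.0348 with no filter). In the 3 later lists 0 genes passed the limma test over all genes, over the list alone or at an unadjusted p under 0.05; Actrt1, Actl7a, Pgk2, Hist1h1t, Oaz3 and Akap4 differed by -0.16 to -0.06 log2.

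The knockout controls were also higher in 4 stress and metabolic lists. These were oxidative stress (median 0.12, camera adjusted p = 0.000425; 4 of 16 called, Gstm1, Gsta4, Cat and Nfe2l2, and 7 adjusted over the list alone), the unfolded protein and integrated stress response (0.14, 0.000425; 2 of 18, Xbp1 and Ddit4, and 8), cholesterol biosynthesis (0.15, 0.0198; 1 of 16, Nsdhl, and 3) and heat shock (0.07, 0.0396; 1 of 21, Hspd1, and 4). In this order they had adjusted p = 0.496, 0.318, 0.535 and 0.496 with an estimated correlation. The heat shock list was lost with a filter of 5 TPM (adjusted p = 0.0703) and median-of-ratios scaling (0.051), and the cholesterol list with a filter of 5 TPM (0.0556); they were lost in 4 and 2 of the 12 fits without 1 unheated library. Xbp1, Ddit4, Hspd1, Gsta4, Cat and Nfe2l2, and above Fcer1g, Rhox5 and Dhh, were lost with a pseudocount of 5 (adjusted p = 0.06 to 0.124), no filter (0.0565 to 0.0891) and quantile normalization (0.0661 to 0.138), and in 8 to 12 of these 12 fits. With no filter Gstm1 (0.0775), Cst9 (0.0611), Hsd3b1 (0.0542) and Hsd3b6 (0.0565) were lost, with quantile normalization Nsdhl (0.0647), and these 5 in 2 to 8 of the 12 fits, Tsx in 3 and Ptgds in 1. Knockout replicate 6 stood apart on the heat shock list (mean log2 5.63, others 5.494 to 5.528) and the unfolded protein response list (4.676, others 4.501 to 4.531). Hspa8 and the sterol enzyme gene Msmo1 were 1.19 and 1.37 times the wild-type mean (adjusted p = 0.0535 and 0.0556). Hspa8, Msmo1, Csf1r, Nfkbia and mt-Nd3 passed with a pseudocount of 0.1 and with a filter of 5 TPM (adjusted p = 0.0344 to 0.0457). A further 4 lists were higher with 0 genes called over all genes: mitochondrially encoded genes (0.22, 0.00158; 7 adjusted over the list alone), interferon-stimulated genes (0.17, 0.00599; 1), inflammatory cytokines (0.26, 0.0396; 1) and extracellular matrix (0.16, 0.0255; 0). In this order they had adjusted p = 0.318, 0.496, 0.496 and 0.567 with an estimated correlation. The cytokine list was lost with a pseudocount of 5 (adjusted p = 0.0673) and in 4 of the 12 fits without 1 unheated library, and the matrix list in 3. On the mitochondrial list knockout replicate 1 stood apart (mean log2 7.342, others 6.943 to 6.987). There mt-Atp6 was listed at 14.54 TPM, against 0 in every other unheated library, which raised the mean of that library. At an unadjusted p under 0.05 the limma counts were 7, 3, 2 and 5. Their leading members, none past the threshold over all genes, stood at 1.17 to 1.74 times the wild-type mean and were mt-Nd3, mt-Nd1, Bst2, Gbp2, Nfkbia, Lcn2, Sparc and Lamb1. In all 14 lists were called. The list of stress granule components did not pass camera (median 0.02, adjusted p = 0.917; 0 of 26 called, 1 adjusted over the list alone), and Ddx3x and Usp10 were 1.34 and 1.17 times the wild-type mean (adjusted p = 0.0697 and 0.0943). In the MAGE family Mageb4 was lower and Mageb16 higher, at 1.25 times the wild-type mean (adjusted p = 0.0471; lost with a pseudocount of 5, 0.087, no filter, 0.0827, and quantile normalization, 0.127, and in 11 of the 12 fits without 1 unheated library), and the list did not pass camera (adjusted p = 0.552, or 0.00505 with a filter of 5 TPM; 5 higher and 1 lower adjusted over the list alone).

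In all, 237 genes were higher and 16 lower in the unheated knockout (1.33% of genes tested; 3041 at an unadjusted p under 0.05), and 0 were higher and 2 lower by at least 2-fold. The 2 were Mageb4 and Mageb10-ps, an unprocessed pseudogene on the same strand of chromosome X at 86299922 to 86301328. It lies inside the Mageb4 gene span, between exons of the longer of its 2 annotated transcripts. It fell from 4.73 ± 0.534 TPM in wild type to 1.06 ± 0.0729 TPM in the knockout (SD, n = 6 each), and its value is uncertain where reads are shared with MAGE paralogs. The next largest fall was Nmnat3, an NAD synthesis enzyme (48.8 ± 2.74 to 34.7 ± 3.82 TPM). The largest rises were Apoc1 (1.54-fold, adjusted p = 0.0273), Ces1d (1.47-fold, 0.00828), the fatty acid binding protein gene Fabp5 (1.46-fold, 0.0357), Npepl1 (1.44-fold, 0.0118), Ly6e (1.39-fold, 0.0452) and Efnb1 (1.44-fold, 0.0416). Of these, only Ces1d and Npepl1 held in all 12 fits without 1 unheated library; Apoc1 was lost in 5 and Fabp5, Ly6e and Efnb1 in 11 each. With no filter these 4 were also lost (adjusted p = 0.0565, 0.0691, 0.0847 and 0.0806). Fabp5, Ly6e and Efnb1 were lost as well with a pseudocount of 5 (0.0914, 0.06 and 0.0865) and quantile normalization (0.0707, 0.0647 and 0.0827). The count moved with every library: without wild-type replicates 1 to 6 in turn, 90, 47, 15, 203, 38 and 137 genes were higher, and without knockout replicates 1 to 6, 76, 62, 83, 76, 91 and 21. With quantile normalization the split was 44 higher and 26 lower. A fit of the 12 unheated libraries alone called 1175 higher and 137 lower. Knockout replicate 6 also stood apart on the first principal component, at -60.9 against -75.3 to -71.8 in its group.

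After heat, transcripts of pachytene and later germ cells were higher in the knockout than in wild type, and those of Sertoli cells and several other somatic lists lower. All 25 round spermatid genes were higher (median log2 difference 1.88, camera adjusted p = 1.69e-08), as were 22 of 27 pachytene and diplotene genes (0.92, 1.97e-05; 1 lower) and 19 of 22 elongating spermatid genes (0.68, 7.32e-06), each list with adjusted p = 0.527 with an estimated correlation. Earlier germ cell lists did not go this way and did not pass: 8 of 10 genes of undifferentiated spermatogonia were lower and 2 higher (median -0.74, adjusted p = 0.124; 0.0081 with no filter), 4 lower and 2 higher of 10 of differentiating spermatogonia (0.897) and 12 lower and 6 higher of 25 of early meiotic prophase (0.811). Tnp2, a transition protein that packs spermatid DNA, was at 1741 ± 531 TPM in heated wild type (SD, n = 4) and 10887 ± 1187 TPM in the heated knockout (n = 5), beside 7701 ± 849.7 and 7569.5 ± 664 TPM without heat. Capza3 was 5.44-fold, Tssk2 2.31-fold and Actl7a 2.16-fold higher. The testis lactate dehydrogenase gene Ldhc stood at 384 ± 142 and 2179.7 ± 309.7 TPM, and Calr3, a chaperone of germ cells, at 14.1 ± 5.99 and 113 ± 18.5 TPM. In the piRNA pathway 13 of 19 genes were higher and 3 lower (adjusted p = 0.0186; adjusted p = 0.604 with an estimated correlation), with Gtsf1 6.82-fold and Mael 3.63-fold higher. Of the 20 Sertoli cell genes 19 were lower (median -0.92, adjusted p = 0.000169; adjusted p = 0.527 with an estimated correlation), Cst12 by 1.89-fold and Tsx by 1.80-fold.

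Further lists were lower in the heated knockout, each with adjusted p = 0.527 with an estimated correlation. In the MAGE family 18 of 20 genes were lower (median -0.74, camera adjusted p = 0.00271), Mageb18 by 2.43-fold. Of the 12 mitochondrially encoded genes 10 were lower (-1.11, 0.004), mt-Nd1 by 2.90-fold and mt-Nd3 by 2.02-fold. The lists of oxidative stress (15 of 16, 0.012; Nfe2l2 and Prdx1 leading), the unfolded protein response (15 of 18, 0.0249; the chaperone genes Hspa5 and Hsp90b1 leading), interferon-stimulated genes (9 of 9, 0.0351; Ifih1, Irf7), endothelium (10 of 12, 0.0351; Cdh5, Pecam1) and extracellular matrix (13 of 18, 0.0351; Sparc, Lamc1) were also lower. With a filter of 5 TPM the unfolded protein response and endothelium lists were lost (adjusted p = 0.0543 and 0.316), and with quantile normalization those of endothelium, interferon and matrix (0.0643, 0.0663 and 0.0713). The interferon list was also lost with a pseudocount of 0.1 (0.0558), and the matrix list without wild-type heat replicate 2 (0.0502). Camera, which sets a list against all other genes, did not pass for Leydig cells (9 of 14 lower, median -0.33, adjusted p = 0.173), leukocytes (14 of 20, 0.0681) or peritubular myoid cells (7 of 9, 0.231). Their list means themselves were lower in the knockout (log2 differences -0.36, -0.46 and -0.36, exact permutation p = 0.0159, 0.0238 and 0.00794, adjusted 0.0185, 0.0238 and 0.0111). These tests used TPM without further scaling. Median-of-ratios scaling shifts this comparison by 0.19 log2, and they were not repeated with it. Of the 26 stress granule components 19 were lower and 4 higher (median -0.59, adjusted p = 0.0505), Fmr1 being 2.43-fold lower and Ybx1 2.16-fold higher. This list lay at the threshold: it passed with a pseudocount of 0.1 (adjusted p = 0.0422), no filter (0.00504), quantile normalization (0.0451) and the replicate number as a block (0.045), and in 4 of the 9 fits without 1 heated library, but not with an estimated correlation (0.604). Heat shock genes were lower in 12 and higher in 3 of 21 (adjusted p = 0.124), with Stip1 1.56-fold lower and Dnajb1 1.65-fold higher. With no filter the heat shock (0.0251), leukocyte (0.00654), junction (0.0133) and p53 (0.0158) lists passed too, and the leukocyte list in 2 of the 9 fits.

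**Figure D3:**
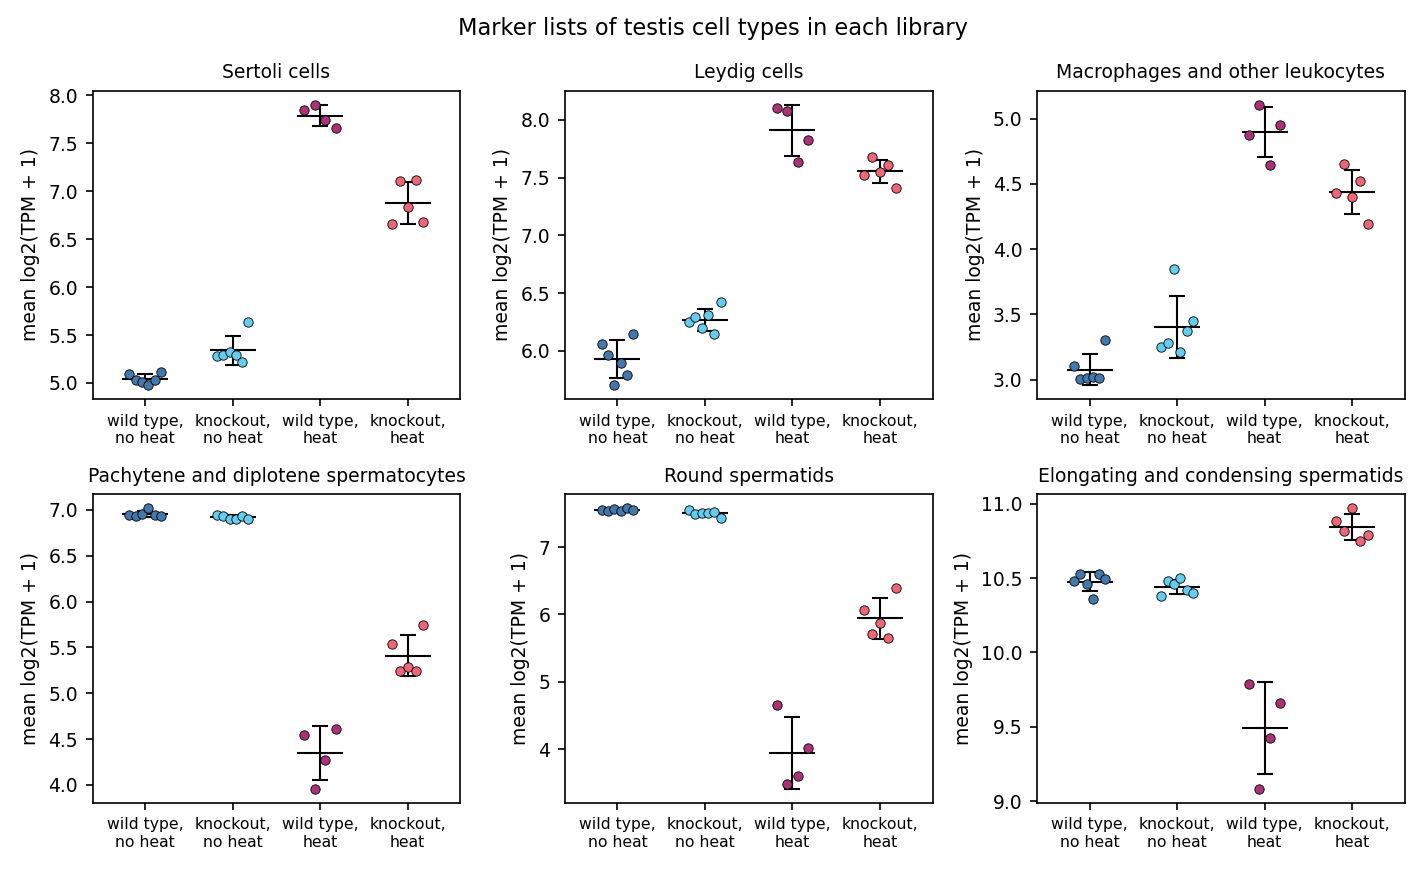
Mean log2(TPM + 1) of 6 marker lists (vertical axes, which do not start at 0) in each of the 21 libraries, by group, with group means and SD in black. Heated knockout libraries lie between the unheated and the heated wild-type libraries for Sertoli cells, pachytene spermatocytes and round spermatids, and above all other groups for elongating spermatids.

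Over all genes, 6534 were higher and 9304 lower in the heated knockout (83.5%), and 3063 and 1198 of them by at least 2-fold. The excess of lower genes shrank with median-of-ratios scaling, to 7418 higher and 7751 lower, and grew with quantile normalization, to 5659 higher and 9744 lower. The largest rises were Ccdc185 (5.61 ± 7.02 TPM in wild type, 135 ± 14.8 TPM in the knockout), Prss52, the sperm outer dense fibre gene Odf3, Cst13, Iqcf6 and Hemgn. The 6 ratios, 16.7-fold (Odf3) to 23.99-fold (Ccdc185), depended on wild-type heat replicate 1 and were 30.4-fold (Cst13) to 63.9-fold (Ccdc185) without it. The largest falls included Mageb10-ps (12.7-fold), Timp1 (4.75-fold), the arginine deiminase gene Padi2 (4.18-fold) and Sept14 (3.93-fold). Spink8 and Defb37, also among them, were set by wild-type heat replicate 3, which held 1280.1 and 324.7 TPM. Without it their log2 differences were -1.64 and -1.24, in place of -3.22 and -2.80. Adjusted over the list alone, 3 in place of 4 genes of differentiating spermatogonia were lower, and the other counts were the same. In all 12 lists were called.

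The difference of the heat effects, tested directly, was significant for 15321 of 18977 genes, 6297 with a more positive and 9024 with a more negative change in the knockout (7207 and 7510 with median-of-ratios scaling). The heat effects of the 2 genotypes, which share no library, were correlated across genes (Pearson r = 0.88, Spearman rho = 0.89; genes are not independent replicates). The slope of knockout on wild type was 0.473 ± 0.0449 (jackknife SE over the 21 libraries). In both genotypes 7065 genes rose, against 3684 for independent lists, and 6773 fell, against 3511. Opposite calls were made for 938 genes, 525 of them lower in wild type and higher in the knockout. The difference was positive for 25 of 25 round spermatid genes (median 1.94, camera adjusted p = 2.05e-08) and 23 of 27 pachytene and diplotene genes (0.90, 1.65e-05). Positive differences were also found for 19 of 22 elongating spermatid genes (0.73, 4.8e-06) and 11 of 19 piRNA pathway genes (0.49, 0.02). The first 3 of these lists had adjusted p = 0.505 with an estimated correlation and the piRNA list 0.543. The difference was 2.71 ± 0.20 log2 for Tnp2, 2.54 ± 0.19 for Capza3, 2.94 ± 0.20 for Calr3, 2.60 ± 0.22 for Ldhc, 1.27 ± 0.09 for Tssk2, 1.19 ± 0.09 for Actl7a, 2.84 ± 0.21 for Gtsf1 and 1.93 ± 0.16 for Mael.

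The difference was negative for 19 of 20 Sertoli cell genes, all of which rose in both genotypes (median -1.18, camera adjusted p = 2.14e-05; Cst12 -1.30 ± 0.10, Tsx -1.18 ± 0.10), for 11 of 14 Leydig cell genes (-0.65, 0.0277; Cyb5a -1.28 ± 0.12, Hsd3b1 -0.98 ± 0.14) and for 17 of 20 leukocyte genes (-0.93, 0.0189; Mrc1 -1.49 ± 0.13, Fcer1g -1.35 ± 0.13). All lists in this paragraph that passed had adjusted p = 0.505 to 0.543 with an estimated correlation. The same held for 17 of 20 MAGE genes (0.00318; Mageb18 -1.41 ± 0.13), 10 of 12 mitochondrially encoded genes (0.00318; mt-Nd1 -1.85 ± 0.14, mt-Nd3 -1.23 ± 0.09), 14 of 16 oxidative stress genes (0.00624; Nfe2l2 -1.34 ± 0.11, Gsta4 -1.46 ± 0.13) and 15 of 18 unfolded protein response genes (0.0126; Xbp1 -1.12 ± 0.10, Pdia4 -0.999 ± 0.09). It held too for interferon-stimulated genes (9 of 9, 0.0201; Ifih1 -1.19 ± 0.14), endothelium (10 of 12, 0.0277; Cdh5 and Pecam1) and extracellular matrix (13 of 18, 0.0201; Sparc and Dcn). The endothelium list was lost with a filter of 5 TPM (adjusted p = 0.239) and quantile normalization (0.0518), and the leukocyte list with a filter of 5 TPM (0.0524). Stress granule components differed in 18 negative and 3 positive calls of 26 (adjusted p = 0.0599), with Ddx3x at -1.64 ± 0.17 and Ybx1 at 1.15 ± 0.07. This list passed with no filter (adjusted p = 0.00476), with quantile normalization (0.0346) and in 4 of the 21 fits without 1 library, but not with an estimated correlation (0.586). In the heat shock list 13 of 21 were negative (adjusted p = 0.0918), led by Hspd1 and Hspa8. With no filter it passed (0.0104), as did junctions, peritubular myoid cells, undifferentiated spermatogonia and p53 targets (0.00476 to 0.0299). Among single genes the largest positive differences were Ccdc185 (4.82 ± 0.44), Prss52, Odf3, Cst13, Iqcf6 and Fhl5, and the largest negative ones Spink8, Defb37, Timp1 (-2.68 ± 0.38), the actin-bundling protein gene Lcp1, Tnfrsf12a and Padi2. Spink8 and Defb37 again rested on wild-type heat replicate 3 (-1.49 and -1.19 without it, in place of -3.06 and -2.75), and Ccdc185 and Odf3 moved without replicate 1 (log2 5.44 and 4.97 in place of 4.82 and 4.36). The difference for Ddx5, -0.33 ± 0.09 (adjusted p = 0.00242), did not pass with median-of-ratios scaling (-0.11, adjusted p = 0.221), nor that for Defb37 with a pseudocount of 5 (0.0712) or no filter (0.0576). Adjusted over the list alone, 2 in place of 1 genes of undifferentiated spermatogonia were positive and 18 in place of 17 leukocyte genes negative. In all 14 lists were called.

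**Figure D4:**
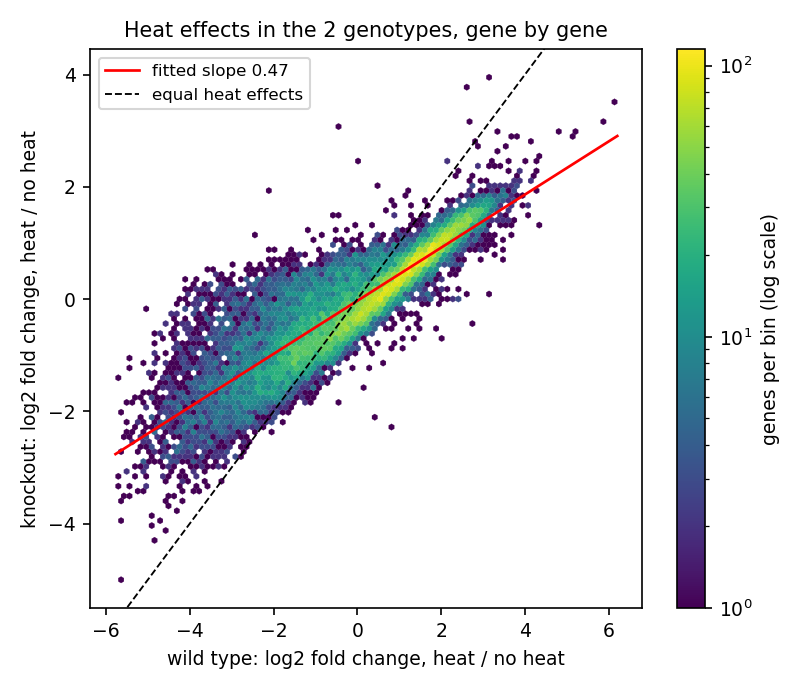
Log2 fold change of heat against no heat in wild type (horizontal axis) and in the knockout (vertical axis) for 18977 genes, coloured by genes per bin on a log scale. The red line is the fitted slope of 0.47 and the dashed line marks equal effects.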

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

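The tests of the Sertoli and Leydig difference, of the degree of heating, of the direction of the differences with median-of-ratios scaling, of the second epididymis list in other heated libraries, of a lower germ cell share, of the Sertoli and Leydig lists without knockout control replicate 6, and of fold changes in TPM without single libraries were chosen after the results were seen. Single libraries were compared with the rest of their group by the gap to the nearest library over the range of the group. Of 144 groups of values tested, 17 held a library apart, and chance flags about 1 in 20 groups, or 7.2 here.

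The heat effect differed between the genotypes for 15321 genes and 14 lists and was mostly smaller in the knockout, with a negative difference for 8005 genes that rose in wild type, G3bp1 (-0.7215 log2) and G3bp2 (-1.039) among them, and a positive one for 5987 that fell, although 938 genes had opposite calls and the median of the elongating spermatid list was 0.66 in the knockout and -0.45 in wild type. Of 100 splits, 1, the real one, gave as many as 15321 genes, and the highest other gave 14615. The same held for the heated genotypes (15838, highest other 15175). This makes chance unlikely, but 100 splits cannot put it below 1 in 100. The slope of knockout on wild-type effects, 0.473, stayed at 0.478 without wild-type heat replicate 3, which argues against epididymal RNA in that library. TPM scaling moves all genes 1 way and cannot change the slope, first set as its test (0.480). It is argued against by differences in both directions with median-of-ratios scaling, positive for 7207 genes and negative for 7510. The difference was negative for 85.4% of genes that rose in wild type and positive for 73.2% of those that fell. These genes were chosen by their wild-type change in the same libraries, which favours these signs. A different germ cell share alone could not be judged from the Sertoli minus Leydig marker difference. Its change from heated wild type to heated knockout was -0.553 log2 (exact permutation p = 0.00794), so the 2 lists did not move alike. But with heat itself the Leydig list rose by less than the Sertoli list in each genotype (-0.76 log2 in wild type, -0.25 in the knockout). Unequal movement of these lists therefore does not decide the question. Heat reaching the 2 genotypes to a different degree cannot be told apart from an effect of Mageb4 loss, since the labels give no heating session and the 2 responses were correlated across genes with r = 0.883.

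Wild-type heat replicate 3 stood apart on the epididymis list, with a mean of 6.318 log2 against 0.03108 to 0.2532 in the other heated wild-type libraries. It held 2126 TPM of Crisp1, 1280.1 of Spink8, 642 of Wfdc10, 551 of Cuzd1, 330 of Ces5a and 136 of Adam7. Rnase9 stood there at 114 TPM, Rnase12 at 113 and Bsph2 at 85.6, against at most 0.26 TPM in any other library. Wfdc10 reached 292 TPM in wild-type heat replicate 1 as well. Gpx5, Lcn8 and Lcn9 were listed at 0, and 6 of the 10 detected genes of the list peaked in replicate 3. A response to heat shared by the testes is argued against, since a second epididymis list, written after this library was seen, moved by -0.185 to -0.045 log2 over unheated wild type in the other heated wild-type libraries and by 2.03 in this one (a mean of -4.78% of its rise), while a response of this testis alone was not tested. Whether the sample held epididymal tissue was not decided by the test set for it, the share of the second list that peaked there. Of 22 detected genes 11, or 50% (95% interval 28.2% to 71.8%), did so, against at most 2 in any other library. The interval spans the bound of 50% set for excluding epididymal tissue, and it treats genes as independent, which transcripts of 1 tissue are not. How far expression in testis lowered the share could not be told. Of the genes under 1 TPM in the other libraries 7 of 13 peaked there, and of those at or above it 4 of 9. But the genes under 1 TPM include some near 0 in every library, such as Gpx5 (at most 0.04 TPM), Adam28 (0.05) and Clpsl2 (0.16). These also lower the share, so it cannot decide.

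Sertoli and Leydig cell genes were higher in the unheated knockout, and several values set knockout control replicate 6 apart from its group. Chance is unlikely for the comparison, since 1 of 100 splits, the real one, gave 253 genes and the highest other gave 40. That number of splits cannot exclude it. Knockout control replicate 6 alone is argued against for these 2 lists: without it they stayed higher by 0.24 and 0.31 log2 (exact permutation p = 0.00216 and 0.00649). For the count of genes it cannot be told apart, since without it 0.0886 of the genes higher were left, but leaving out any of 6 of the 11 other libraries also left under 0.33 (lowest 0.0633). Whether a lower germ cell share was the whole cause could not be told. Of 4 somatic lists 2 moved apart from the Sertoli list (endothelium -0.23 log2, adjusted exact permutation p = 0.00866, and peritubular myoid -0.15, 0.01732). Leydig (0.04, 0.687) and leukocytes (0.03, 0.846) did not. With heat the same 2 lists also moved apart from the Sertoli list, endothelium by -1.33 and myoid by -1.48 log2 in wild type, and each by -0.77 in the knockout. Unequal shifts of these lists therefore do not decide the question. An effect of Mageb4 loss on somatic cells and a lower germ cell share, as the whole or a part, stay open.

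The differences of the heat effect for Mageb4, -1.592, and Ddx5, -0.3287, are not read as a smaller response, although Mageb4 is among the 8005 genes. Mageb4 was near 0 TPM in the knockout with or without heat. Ddx5 fell by more in the knockout, a difference lost with median-of-ratios scaling (limma adjusted p = 0.221). For heat in wild type chance is unlikely but not excluded (17385 genes, 1 of 100 splits, highest other 15609), and so for heat in the knockout (15708 genes, 1 of 100 splits, highest other 12618). The other libraries apart were as follows, with the range of the rest of their group in parentheses. Knockout control replicate 6 was high on the list means of heat shock genes (5.63; 5.494 to 5.528), the unfolded protein response (4.676; 4.501 to 4.531), differentiating spermatogonia (4.03; 3.639 to 3.711), Sertoli cells (5.633; 5.218 to 5.32) and junctions (4.854; 4.689 to 4.744). It was also high on the first principal component (-60.93, with -75.28 to -71.79 in its group), the median-of-ratios factor (1.012; 0.9525 to 0.9735) and G3bp1 TPM (16.48; 12.86 to 13.7). Knockout control replicate 3 was high for leukocytes (3.851, with 3.212 to 3.447) and replicate 1 for mitochondrially encoded genes (7.342, with 6.943 to 6.987). The mean of replicate 1 was raised by mt-Atp6, listed at 14.54 TPM against 0 in the rest of its group. Wild-type control replicate 4 was high for the MAGE family (1.987; 1.887 to 1.921), early meiotic prophase (5.133; 4.957 to 5.022) and pachytene spermatocytes (7.019; 6.935 to 6.952). Wild-type control replicate 6 was high for cholesterol biosynthesis (4.755; 4.473 to 4.55) and leukocytes (3.305; 3.001 to 3.103), and replicate 2 for the epididymis list (1.234; 0.6629 to 0.7166).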

How the results depend on the processing

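All alternatives here were planned, and none was chosen after the results were seen. The number of replicates, not depth, could be judged, because TPM keeps no depth. No named gene or list changed direction while called. For heat in each genotype, though, the direction that held most of the called genes depended on the scaling. Of the values of main results, 318 under other settings and 480 with 1 library left out lay on the same side of the threshold or within 1.5 times the count, and 37 and 24 did not. For named genes under other settings 1888 values stayed on their side, 38 no longer passed and 35 newly passed (2697, 117 and 1 with 1 library left out). For single lists the numbers were 894, 94 and 37 (1605, 16 and 17). For heat in wild type, a pseudocount of 5 gave 3823 genes higher and 3863 lower by at least 2-fold, and no filter gave 13516 higher, with more genes tested; for heat in the knockout a pseudocount of 5 gave 993 and 1906. A higher pseudocount shrinks the fold changes of low genes by construction. Mageb4 in the heated knockout passed with a pseudocount of 0.1 (0.61 log2, adjusted p = 0.00174; range over its alternatives 0.00174 to 0.388), and Mageb4 has no value under the filter of 5 TPM. For knockout against wild type after heat, a pseudocount of 5 gave 1702 and 503 genes by at least 2-fold and median-of-ratios scaling 504 lower. For the difference of the heat effects the values were 1807, 1038 and 1111. With an estimated correlation 0 lists were called in any of the 5 comparisons, against 16, 17, 14, 12 and 14 (limma camera; 0, 1, 4, 0 and 0 at an unadjusted p under 0.05).

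The comparison of unheated groups moved most. Against 237 higher and 16 lower, the counts were 444 and 10 (1 at least 2-fold higher) with a pseudocount of 0.1, and 86 higher (0 at least 2-fold lower) with 5. They were 66 higher with no filter, and 6 lower (1 at least 2-fold) with a mean of at least 5 TPM. Median-of-ratios scaling gave 30 lower and quantile normalization 44 and 26. A robust fit with array weights gave 2097 and 200 (2 and 6 at least 2-fold), and only the groups compared 1175 and 137. All 253 genes called were also called in these last 2 fits, and 56 of them with quantile normalization. Leaving out 1 library gave 15 to 203 higher, 4 to 9 lower and 0 to 1 at least 2-fold higher. G3bp2 in this comparison passed with the robust fit (0.15 log2, adjusted p = 0.0286; range over its alternatives 0.0286 to 0.597). The main fit shares 1 spread per gene over all groups, and the heated groups spread more (median SD 0.147 and 0.179 log2, against 0.110 in each unheated group). The fit of only the groups compared leaves this spread out. How far it accounts for these changes was not tested.

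The replicate numbers did not pair the libraries: of 28 pairs with the same number 4 had a correlation of deviations over 0.1 (-0.228 to 0.314), and 1 of 21 libraries correlated best with its own number. With the replicate number as a block, 173 genes were higher, 8 lower and 1 at least 2-fold higher in the unheated knockout. Mageb16, Efnb1, Ddit4, Cat, Nfe2l2, Rhox5 and Dhh were lost (adjusted p = 0.0532 to 0.0774) and Msmo1 passed (0.0252).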

Other observations

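The test of X-linked genes was chosen before its result was seen. X-linked genes moved apart from the autosomes. In heated wild type the median log2 fold change of 871 X-linked genes was 1.33, against 0.05 for 17689 autosomal genes, and 574 were higher and 250 lower. In the heated knockout the X-linked median was 0.65 (566 higher, 192 lower). Without heat 34 X-linked genes were higher and 2 lower in the knockout (median 0.05), and after heat 225 were higher and 550 lower (median -0.60). As a hypothesis, the rise in heated wild type may follow from a loss of meiotic and later germ cells, in which the X chromosome is silenced. The X-linked median in heated wild type lay at percentile 100 of 10000 autosomal lists matched on expression, of which the central 95% ended at 0.327. The test could not tell this from induction of X-linked genes in the cells that remain.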
